A study of Rattus norvegicus with 6 samples.

How the data were processed

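PolyA RNA from whole lung tissue of male Sprague-Dawley rats was sequenced in 6 samples, 3 from saline control rats and 3 from rats given 1 dose of monocrotaline (MCT). Per the labels' protocols, the dose was 60 mg/kg, the rats weighed 200 to 250 g and the lungs were taken after 4 weeks. The labels differ on the route of the MCT injection, which is intraperitoneal in the treatment protocol and in the series design and subcutaneous in the sample characteristics. Saline was given subcutaneously per the labels, so the route of injection may have differed between the groups. Libraries were made from fragmented mRNA with random primers, per the labels' protocols, and whether they keep strand is not given in the sources used here. Groups and replicate numbers come from the sample titles.

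The deposited table holds an estimated count and an FPKM value for each of 23802 genes in each sample, per the file headers and the values. The submitters' processing notes name Bowtie2, TopHat2 2.0.3.12 and the genome build Rnor_6.0. The tool that assigned reads to genes, the annotation release and the handling of reads that map to more than 1 place are not given in the sources used here. Of the deposited estimated counts above 0, between 90.7% and 91.5% per sample were whole numbers, and all were rounded to whole numbers for the tests. The tests had been fixed for raw counts before the files were seen. The FPKM values were made by the authors. The gene length implied by count, column total and FPKM agreed within 1% between libraries for 83.8% of the 8696 genes with an FPKM of at least 5 in every library. Gene symbols and pathway names were taken from the deposited table. Loci with an assembled-transcript identifier took between 1.74% and 2.16% of each library's counts. Genomic positions are not given here, since no genome or annotation of the files' build was used.

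Summed counts were 15336719, 13525912 and 17916134 in control replicates 1 to 3, and 14668886, 17096157 and 14332930 in MCT replicates 1 to 3. Between 17674 and 17950 genes had a count in each library. Mitochondrial genes took 3.55% to 5.21% of the counts and the 10 most abundant genes 8.15% to 11.7%. The counts carry no molecular identifiers, so a floor based on them covers counting error only. For a gene with no count in a group, the fold was computed against a floor of 3 counts over the group.

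The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on all 6 samples with TMM normalization and no covariates. Genes were kept by filterByExpr with the group, a minimum count of 10 and a minimum total count of 15, which left 15250 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values given for genes come from this test unless another is named. Levels are TMM-normalized CPM, counts scaled to the effective library size, with the SD over the 3 samples of a group, and log2 fold changes are MCT over control with their standard error. Nothing in the labels says that each sample is a separate animal or that none was pooled, so p-values measure the spread between these samples, which may be technical in part.

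Before the data were examined, 35 gene lists, the named-gene rule, the tests and the alternatives were fixed. The lists were mitosis, DNA replication, p53 targets, fibrillar and vascular matrix, smooth muscle contractile, pericyte, fibroblast, endothelium, capillary endothelium, lymphatic endothelium, alveolar type 1, alveolar type 2, club and secretory epithelium, ciliated epithelium, macrophage, neutrophil, mast cell and basophil, T and NK cell, B and plasma cell, erythroid, cardiac muscle, mesothelium and adipose, chemokines and cytokines, interferon response, MHC class II presentation, complement, BMP and TGF-beta signalling, genes of heritable pulmonary arterial hypertension, vasoactive signalling, growth factors and receptors, glycolysis and hypoxia response, fatty acid oxidation, oxidative stress response, immediate early and stress, and circadian clock. They held 759 different symbols, of which 718 were in the table and 667 were tested. Some genes stand in more than 1 list. Each list was tested with limma's camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated for each list and fry were the alternatives.

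The genes named are Pbk, from the series title, the 10 genes with the largest rise and the 10 with the largest fall, and for each list the 3 tested members with the smallest p and the tested member with the highest mean CPM. The genes with the largest rise or fall were taken among called genes with a gene name, a mean of at least 5 CPM and no overlap between the groups. Other genes are named with the words that they are outside the rule, and were chosen after their values were seen. Some list members are counted but not reported here by name.

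Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios size factors, library sizes only, no filter on low counts, a stricter filter with a mean of at least 50 counts, an adjusted p under 0.01, the replicate number as a block, each sample left out in turn, and limma-trend on the deposited FPKM values as log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1.

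The tests were checked on simulated counts for the 15250 genes with the means and library sizes of these 6 samples and 200 changed genes with a mean count of at least 20. For MCT against control, edgeR recovered 58% of the genes changed 2-fold and 96% of those changed 4-fold, with 12 false calls among 166. DESeq2 recovered 72% and 96%, with 35 false calls among 203, and limma-voom 59% and 95%, with 14 among 168. With no effect simulated, camera called 0 of the 35 lists. With the mitosis list raised 2-fold, camera called it at an adjusted p of 8.07e-70 and 1 other list. Simulated genes vary independently, so this check says nothing on lists whose genes vary together between animals. KEGG pathways of 10 to 300 tested genes were tested by a hypergeometric test against tested genes with a pathway, a step chosen after seeing the data, as was its repeat with 1 locus per symbol and per set of identical counts.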

Results

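RNA-seq profiles of whole lung were compared between 3 saline control samples and 3 samples from rats taken 4 weeks after 1 dose of 60 mg/kg MCT, a plant alkaloid used to produce pulmonary arterial hypertension in rats. The series title names PDZ-binding kinase (Pbk) in vascular remodelling, and the design asks which transcripts differ in the lungs of MCT-treated rats. Summed counts ranged from 13525912 to 17916134 per sample. The first principal component held 56.9% of the variance and parted the groups, with controls from -45 to -37 and MCT samples from 24.2 to 63.6. Every pair of samples within a group differed by more than sampling noise, with a chi-square per degree of freedom of 23.2 to 52.6, so no pair was merged as repeat runs of 1 library.

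Pbk, a serine/threonine kinase active in dividing cells, was 6.99-fold higher in MCT lungs. Its level (ENSRNOG00000015308) was 2.35 ± 0.301 CPM (SD, n = 3) in control lungs and 16.6 ± 3.4 CPM (SD, n = 3) in MCT lungs. The log2 fold change was 2.80 (SE 0.23, adjusted p = 0.000682, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and all 3 MCT samples lay above all 3 controls. These levels rest on 30 to 50 counts per control sample and 200 to 301 per MCT sample.

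**Figure D1:**
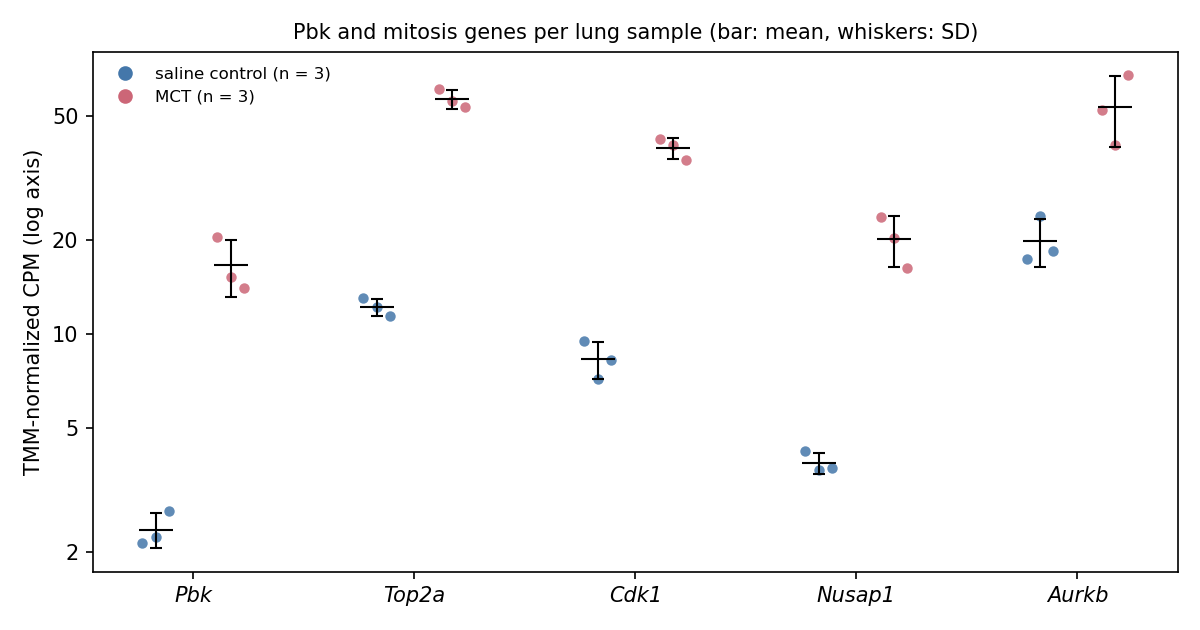
TMM-normalized CPM of Pbk and 4 mitosis genes on a log axis, with a point for each of the 3 saline control (blue) and 3 MCT (red) lung samples, a bar for the group mean and whiskers for the SD. For each gene the MCT points lie above the control points, with Top2a at 12.2 CPM in control and 56.6 CPM in MCT lungs on average.

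Genes of cell division rose together. In the mitosis list 27 of 29 tested members rose and 0 fell, by the edgeR test and also adjusted over the list alone (camera adjusted p = 1.66e-46, and adjusted p = 0.0301 with an estimated correlation). Top2a, the topoisomerase that untangles replicated DNA, rose 4.64-fold, from 12.2 ± 0.773 to 56.6 ± 3.95 CPM (SD, n = 3). The mitotic kinase gene Cdk1 rose 4.75-fold, the spindle gene Nusap1 5.19-fold and Aurkb 2.69-fold. The members that did not pass were Kif23, with a log2 fold change of 0.38, and Ccnb2, with 0.20, both outside the rule for named genes. The Ccnb2 value rests on an assembled-transcript locus with 9 to 31 counts per sample, and its sign turned without control replicate 2 or MCT replicate 2. Among DNA replication genes 13 of 24 rose, 11 did not pass and 0 fell, and 19 rose when adjusted over the list alone (camera adjusted p = 1.38e-11). This call was lost at adjusted p = 0.123 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, rose 8.38-fold, Uhrf1 4.7-fold and the helicase subunit gene Mcm5 3.27-fold. Pcna, the list's most abundant member, had a log2 fold change of 0.45 and did not pass (adjusted p = 0.06), though it was called without MCT replicate 2 (adjusted p = 0.0402) and with DESeq2 (adjusted p = 0.0336).

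Of 19 tested p53 targets, 9 rose, 1 fell and 9 did not pass, against 11 higher and 2 lower adjusted over the list alone (camera adjusted p = 2.44e-08, and adjusted p = 0.0301 with an estimated correlation). The nuclease gene Aen rose 3.17-fold, the stress-induced cytokine gene Gdf15 4.93-fold and the pro-apoptotic Bax 1.89-fold, while Btg2 had a log2 fold change of 0.15 (adjusted p = 0.461). The cell cycle inhibitor Cdkn1a rose by 1.76 (log2) and Perp fell by 0.7, both outside the rule. Without control replicate 2 the call of Cdkn1a ended (adjusted p = 0.073), and without control replicate 3 that of Perp (adjusted p = 0.0647).

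Over all genes, 1221 of the 15250 tested were higher in MCT lungs and 779 were lower, 681 and 358 of them by at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The groups did not overlap in 35.4% of the tested genes, where chance gives 10%. These counts depended on the samples held: there were 562 genes higher in MCT lung and 273 genes lower in MCT lung without control replicate 2, 481 and 212 without control replicate 3, 712 and 343 without MCT replicate 1, and 735 and 324 without MCT replicate 3. By at least 2-fold, the counts were 423 and 183 without control replicate 2, 390 and 165 without control replicate 3, and 205 were lower without MCT replicate 1.

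Of the 10 largest rises, 6 were in mast cell proteases. Cma1 rose by 6.41, Mcpt1l1 by 6.33, Cpa3 by 5.37, Mcpt8l2 by 5.10 and Tpsab1 by 5.03 (log2), and Mcpt1 rose 32.1-fold. Mcpt1 and Mcpt1l1, Mcpt8l2 and Mcpt8, and Tpsab1 and Tpsb2 are close copies, and the split of reads between them is uncertain. Spp1, the gene of osteopontin, rose by 5.49, from 8.25 ± 2.48 CPM in controls to 797, 119 and 203 CPM in MCT replicates 1 to 3. The remaining rises were Cd209a by 5.12, Fcrl2 by 5.12 and TARM1 by 4.95. More than 1 locus carries the name Cd209a, and reads may be shared between them. A single sample moved several of these values: without control replicate 1, Cma1 stood at 7.30, Mcpt1l1 at 6.97 and TARM1 at 5.55. Without MCT replicate 1, Spp1 stood at 4.28, Cpa3 at 4.68 and Cd209a at 4.27, and without MCT replicate 3 Fcrl2 stood at 4.27. The call of Fcrl2 ended without control replicate 2 (adjusted p = 0.052) and without control replicate 3 (adjusted p = 0.0506), and with limma-voom (adjusted p = 0.0889). Over all alternatives the lowest values were 3.02 for Cd209a, 2.41 for Fcrl2 and 1.98 for TARM1, each below its lowest with a sample left out.

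The largest fall was in Upk3b, which fell 19.4-fold, and Upk1b fell 10.2-fold, both uroplakins made by mesothelium. Kcnk2, a potassium channel gene, fell 11.9-fold, the B cell adaptor gene Bank1 9.82-fold and Igfbp6 8.88-fold. Hpgd, whose enzyme breaks down prostaglandins, fell from 130 ± 23.8 to 14.9 ± 4.49 CPM (SD, n = 3). Lrrn1 fell 8-fold, Gckr 7.89-fold and Gpihbp1, which holds lipoprotein lipase on capillary endothelium, 7.59-fold. Armcx1 fell by 3.59 (log2), but this call ended without control replicate 1 (adjusted p = 0.0524), 2 (adjusted p = 0.0592) or 3 (adjusted p = 0.0524), and with DESeq2 (adjusted p = 0.054), and the value was -4.61 without MCT replicate 3.

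Among the 35 lists, camera with the preset correlation called 15 higher and 7 lower. With an estimated correlation 4 stayed called higher (mitosis, p53 targets, fibrillar and vascular matrix, lymphatic endothelium) and 1 lower (mesothelium and adipose). The adjusted p rose even where the estimate lay below the preset value, as for p53 targets at -0.0454 (from 2.44e-08 to 0.0301). A higher correlation was therefore not all that raised these p-values. With fry, which tests a list by itself, 8 of the calls ended: endothelium, capillary endothelium, alveolar type 1, alveolar type 2, neutrophil, T and NK cell, chemokines and cytokines, and immediate early and stress (adjusted p = 0.0508 to 0.219). Splits of the samples that mix the groups also gave 6 to 22 called lists with the preset correlation, so a camera call with that setting is weak evidence by itself.

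**Figure D2:**
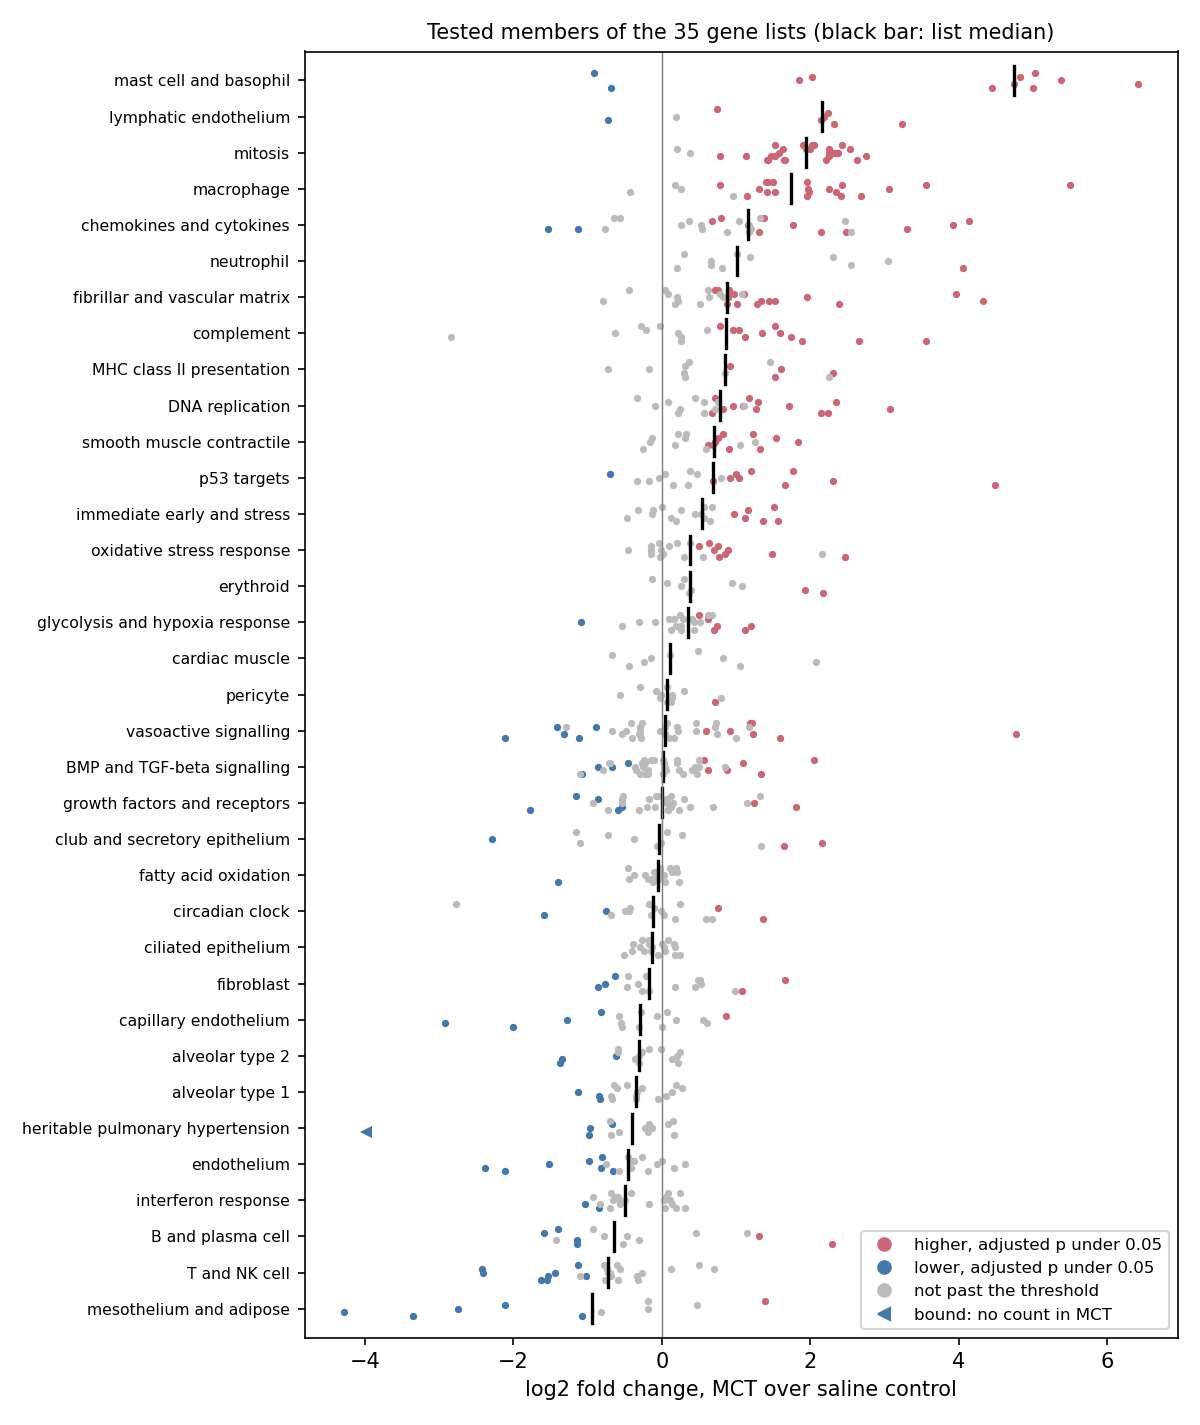
Log2 fold change (MCT over saline control) of each tested member of the 35 lists, with lists sorted by their median (black bar) and members coloured by direction where the edgeR adjusted p was under 0.05. The median was highest for the mast cell and basophil list at 4.74 and lowest for the mesothelium and adipose list at -0.946, and the triangle marks the bound for Gdf2, which had no count in MCT lungs.

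Mast cell transcripts rose while some genes shared with other cells fell. In the mast cell and basophil list 9 of 11 tested members rose and 2 fell, also adjusted over the list alone (camera adjusted p = 7.99e-15). The list's call was lost at adjusted p = 0.13 with an estimated correlation. Cma1, the chymase gene, rose from 2.29 ± 1.91 to 195 ± 65.4 CPM, and Cpa3, a carboxypeptidase of mast cell granules, from 7.84 ± 1.99 to 324 ± 223 CPM (SD, n = 3). Outside the rule and the protease families, the IgE receptor genes Ms4a2 and Fcer1a rose by 4.82 and 4.45 (log2), which became 4.19 and 3.72 without MCT replicate 1. Without that sample Cpa3 stood at 4.68, and without control replicate 1 Cma1 stood at 7.30. The genes that fell were Kit, the stem cell factor receptor, by 0.69, and Gata2 by 0.91, the latter outside the rule. The call of Kit ended without control replicate 2 (adjusted p = 0.106), control replicate 3 (adjusted p = 0.103), MCT replicate 2 (adjusted p = 0.0639) or MCT replicate 3 (adjusted p = 0.113). That of Gata2 ended without control replicate 2 (adjusted p = 0.0732), MCT replicate 1 (adjusted p = 0.0669) or MCT replicate 3 (adjusted p = 0.0683).

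Some transcripts of mesothelium, the lining of the lung surface, fell. In the mesothelium and adipose list 5 of 10 tested members fell, 1 rose and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 1.72e-08, and adjusted p = 0.0301 with an estimated correlation). Upk1b fell from 26.2 ± 1.87 to 2.55 ± 0.0943 CPM and Upk3b from 14.8 ± 2.81 to 0.75 ± 0.476 CPM (SD, n = 3). Lrrn4 fell 6.71-fold, and Msln, the gene of mesothelin, fell 4.32-fold, the latter outside the rule. Rspo1, outside the rule, fell by 1.08 (log2). Cfd, an adipocyte and macrophage gene outside the rule, rose 2.61-fold, and Krt19 had a log2 fold change of -0.19 (adjusted p = 0.346). Wt1, outside the rule, had -0.18 (adjusted p = 0.874). It stood at 2.99, 2.09 and 2.91 CPM in control replicates 1 to 3 and at 4.54, 0.533 and 2.03 CPM in MCT replicates 1 to 3.

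**Figure D3:**
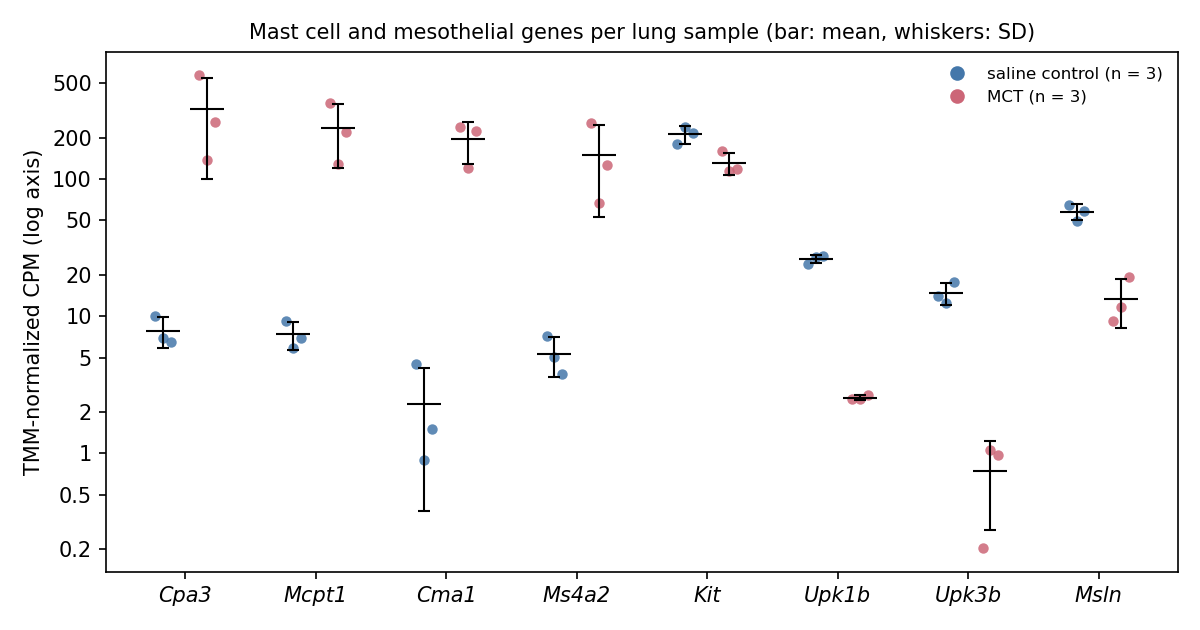
TMM-normalized CPM of 5 mast cell genes (Cpa3, Mcpt1, Cma1, Ms4a2, Kit) and 3 mesothelial genes (Upk1b, Upk3b, Msln) on a log axis, with a point for each of the 3 saline control (blue) and 3 MCT (red) samples, a bar for the mean and whiskers for the SD. Cma1 rose from a mean of 2.29 to 195 CPM and Upk1b fell from a mean of 26.2 to 2.55 CPM.

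Part of the endothelial transcripts fell. In the endothelium list 7 of 19 tested members fell, 0 rose and 12 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 1.55e-07). With an estimated correlation this call was lost (adjusted p = 0.334 with an estimated correlation). Tek, the angiopoietin receptor, fell 5.19-fold, from 534 ± 25.7 to 103 ± 44.8 CPM, and Calcrl, a receptor subunit for adrenomedullin, fell 4.32-fold, from 976 ± 86.7 to 226 ± 61.7 CPM (SD, n = 3). The phosphatase gene Ptprb fell 2.88-fold. Cldn5, the most abundant member, had a log2 fold change of -0.37 (adjusted p = 0.306). Outside the rule, Pecam1, measured on an assembled-transcript locus, had 0.17 (adjusted p = 0.76) and Vwf 0.00 (adjusted p = 0.997). Without MCT replicate 2 both turned, Pecam1 to -0.25 (adjusted p = 0.491) and Vwf to -0.38 (adjusted p = 0.113), and Vwf turned in other alternatives as well.

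**Figure D4:**
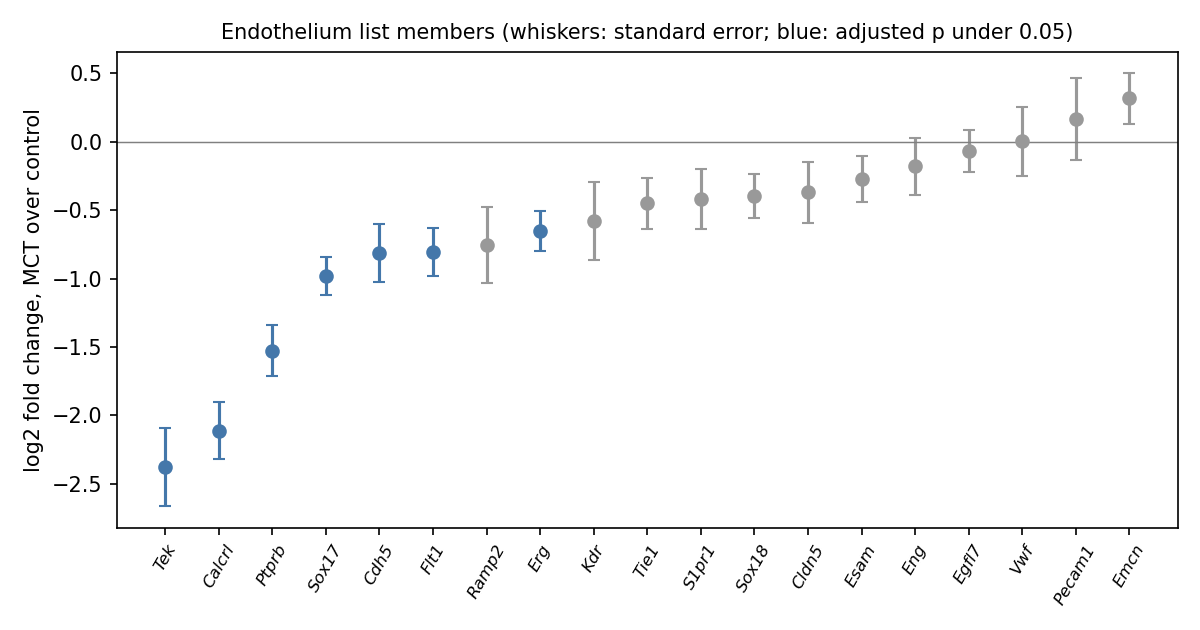
Log2 fold change (MCT over saline control, 3 samples each) of the 19 tested endothelium list members, with whiskers for the standard error and blue where the edgeR adjusted p was under 0.05. Values run from -2.38 for Tek to 0.32 for Emcn.

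In the capillary endothelium list 4 of 16 tested members fell, 1 rose and 11 did not pass, against 5 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.00148, but adjusted p = 0.334 with an estimated correlation). Gpihbp1 fell from 43.7 ± 7.01 to 5.76 ± 1.67 CPM and Tmem100 from 585 ± 40 to 146 ± 19.3 CPM (SD, n = 3). Aplnr, the apelin receptor, fell 2.43-fold, a call that ended without control replicate 2 (adjusted p = 0.0633) or 3 (adjusted p = 0.0639). Outside the rule, Apln rose by 0.86 and Foxf1 fell by 0.82. The call of Apln ended without control replicate 1 or 2 or MCT replicate 3 (adjusted p = 0.0523 to 0.0936), and that of Foxf1 without any 1 of the controls, MCT replicate 1 or MCT replicate 3 (adjusted p = 0.0556 to 0.117). The most abundant member, Cyp4b1, had a log2 fold change of -0.55 (adjusted p = 0.418).

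Lymphatic endothelial transcripts rose instead: 6 of 8 tested members were higher, 1 lower and 1 did not pass, also adjusted over the list alone (camera adjusted p = 1.38e-11, and adjusted p = 0.0301 with an estimated correlation). Ccl21, a chemokine of lymphatic vessels, rose from 64.2 ± 12.9 to 601 ± 45.7 CPM (SD, n = 3), Mmrn1 rose 4.4-fold and Prox1, the lymphatic master transcription factor, 4.56-fold. Pdpn had a log2 fold change of 0.19 and did not pass. The member that fell was Lyve1, outside the rule, by 0.72. Its call ended without control replicate 1 (adjusted p = 0.064), 2 (adjusted p = 0.0515) or 3 (adjusted p = 0.07), and without MCT replicate 1 (adjusted p = 0.0883) or 3 (adjusted p = 0.0938).

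Matrix and contractile transcripts rose. In the fibrillar and vascular matrix list 17 of 30 tested members rose, 0 fell and 13 did not pass, against 21 higher and 1 lower adjusted over the list alone (camera adjusted p = 4.35e-13, and adjusted p = 0.0301 with an estimated correlation). Fn1, the gene of fibronectin, rose from 588 ± 59.5 to 3084 ± 679 CPM (SD, n = 3), the gelatinase gene Mmp2 rose 2.52-fold and the crosslinking enzyme gene Loxl1 1.85-fold. Sparc, the most abundant member, had a log2 fold change of 0.51 and did not pass (adjusted p = 0.113), but was called with DESeq2 (adjusted p = 0.019). In the smooth muscle contractile list 10 of 20 tested members rose, 0 fell and 10 did not pass, against 13 higher adjusted over the list alone (camera adjusted p = 2.82e-06, but adjusted p = 0.179 with an estimated correlation). Smtn rose 1.87-fold, Myl9 1.54-fold and Tpm2 1.64-fold, the last of which was not called without control replicate 3 (adjusted p = 0.0515). Tagln had a log2 fold change of 0.59 (adjusted p = 0.0541) and was called without MCT replicate 2 (adjusted p = 0.0106) and with DESeq2 (adjusted p = 0.00918).

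The pericyte and fibroblast lists were not called. Of 13 pericyte genes 1 rose, 0 fell and 12 did not pass, with 1 higher adjusted over the list alone (camera adjusted p = 0.53). The gene that rose, Postn, lost its call without control replicate 2 (adjusted p = 0.0659). Of 17 fibroblast genes 2 rose, 3 fell and 12 did not pass, against 6 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.913). Its median was -0.173, while its mean was 0.102 and camera's direction was up. Scara5 rose 2.12-fold and Vegfd, outside the rule, rose by 1.67 (log2). Col13a1 fell by 0.86, Limch1 by 0.76 and Npnt, outside the rule, by 0.63. The calls of Col13a1 and Limch1 ended without any 1 of the controls, MCT replicate 1 or MCT replicate 3 (adjusted p = 0.0535 to 0.114). Those of Npnt and Vegfd ended without control replicate 2 or 3 or MCT replicate 1 or 3 (adjusted p = 0.0521 to 0.14), and Vegfd stood at 2.32 without control replicate 1. On both FPKM scales Npnt was not called (adjusted p = 0.0508 and 0.0517).

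Alveolar epithelial lists had lower medians. In the alveolar type 1 list 3 of 17 tested members fell and 14 did not pass, with 3 lower adjusted over the list alone (camera adjusted p = 0.00686). The list's call was lost at adjusted p = 0.607 with an estimated correlation and without MCT replicate 1 (adjusted p = 0.0704). Col4a3 fell by 0.83, and this call ended without control replicate 1 (adjusted p = 0.0584), control replicate 3 (adjusted p = 0.0914), MCT replicate 1 (adjusted p = 0.0726) or MCT replicate 3 (adjusted p = 0.0853). Lmo7 fell by 0.84 and Rtkn2 by 1.13, calls that ended without any of these same samples (adjusted p = 0.0576 to 0.143), that of Rtkn2 also without control replicate 2 (adjusted p = 0.0535), with limma-voom, the stricter filter and both FPKM scales (adjusted p = 0.0515 to 0.0755). In the alveolar type 2 list 3 of 15 fell and 12 did not pass, with 4 lower adjusted over the list alone (camera adjusted p = 0.0138, but adjusted p = 0.498 with an estimated correlation). Etv5, a transcription factor of type 2 cells, fell 2.58-fold, the phosphate transporter gene Slc34a2 2.55-fold and the lipid transporter gene Abca3 1.54-fold. The calls of Slc34a2 and Abca3 ended without any 1 of the controls or MCT replicate 2, and that of Abca3 also without MCT replicate 1 (adjusted p = 0.06 to 0.15) and with the stricter filter (adjusted p = 0.0504). The surfactant gene Sftpc, outside the rule, had a log2 fold change of -0.59 (adjusted p = 0.209), and the type 1 marker Ager -0.27 (adjusted p = 0.607).

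Airway lists were not called. Of 12 club and secretory genes 2 rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.834). Hp, the gene of haptoglobin, rose 3.14-fold, Bpifb1 rose by 2.15 and Scgb3a1 fell by 2.29 (log2). The call of Bpifb1 ended without any 1 of the controls, MCT replicate 1 or MCT replicate 3 (adjusted p = 0.0906 to 0.136), and with limma-voom and both FPKM scales (adjusted p = 0.106 to 0.16). That of Scgb3a1 ended without any 1 of the controls, MCT replicate 1 or MCT replicate 2 (adjusted p = 0.0586 to 0.166), and its value was -3.23 without MCT replicate 3. It also ended with DESeq2, the stricter filter and log2(FPKM + 0.1) (adjusted p = 0.0514 to 0.0529). Scgb1a1, the main club cell secretory protein gene, had a log2 fold change of -0.37 (adjusted p = 0.467). Of 19 ciliated genes 0 passed in either direction with edgeR, over all genes or adjusted over the list alone, and 0 at an unadjusted p under 0.05, with DESeq2 or with limma-voom (camera adjusted p = 0.433), although the list was called lower without MCT replicate 3 (adjusted p = 0.00231). Tppp3, the most abundant member, had a log2 fold change of -0.51 (adjusted p = 0.198).

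Macrophage transcripts were higher. In that list 20 of 24 tested members rose, 0 fell and 4 did not pass, against 21 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.39e-25, but adjusted p = 0.123 with an estimated correlation). C1qc and C1qa, which encode parts of the first complement component, rose 5.35-fold and 5.08-fold. The lipid chaperone gene Fabp4 rose 8.3-fold, and Ctsd, a lysosomal protease gene, from 999 ± 205 to 2694 ± 330 CPM (SD, n = 3).

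In the neutrophil list 1 of 11 tested members rose, 0 fell and 10 did not pass, with 1 higher adjusted over the list alone (camera adjusted p = 0.00514, but adjusted p = 0.445 with an estimated correlation). The gene that rose was Lcn2, by 4.06 (log2), which epithelium also makes. S100a9, a calcium-binding protein of neutrophils, stood at 456, 36.5 and 22.4 CPM in MCT replicates 1 to 3 and did not pass (log2 fold change 3.05, adjusted p = 0.086). Its log2 fold change was 0.51 without MCT replicate 1 (adjusted p = 0.317), and it was called without MCT replicate 2 (adjusted p = 0.0416) or 3 (adjusted p = 0.0452).

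In the T and NK cell list 8 of 24 tested members fell, 0 rose and 16 did not pass, against 13 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.16e-06, but adjusted p = 0.352 with an estimated correlation). Prf1, the gene of perforin, fell 2.91-fold, the transcription factor gene Tbx21 2.89-fold and the NK receptor gene Ncr1 2.7-fold, the last of which was not called without control replicate 3 (adjusted p = 0.0501). In the B and plasma cell list 2 of 14 rose, 4 fell and 8 did not pass, against 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.284). Without control replicate 1 the list was called lower (adjusted p = 0.00461). The members that rose were Jchain, the joining chain of secreted antibodies, 4.9-fold, and Mzb1, a plasma cell gene, 2.47-fold, while Cr2, the complement receptor of B cells, fell 2.2-fold. Outside the rule, the B cell genes Ms4a1 and Cd79b fell by 1.59 and 1.14 (log2). Both calls ended without control replicate 2 or 3 or MCT replicate 2 or 3, and that of Cd79b also without MCT replicate 1 (adjusted p = 0.0561 to 0.162), with limma-voom, the stricter filter and both FPKM scales (adjusted p = 0.0512 to 0.0893).

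Of 10 erythroid genes 2 rose, 0 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.117). The list was called higher without MCT replicate 3 (adjusted p = 0.00115) and with no filter (adjusted p = 0.041). Slc4a1, a red cell membrane gene, rose by 2.17 (log2), a call that ended without any 1 of the controls or MCT replicate 1 (adjusted p = 0.0696 to 0.0809), and with limma-voom (adjusted p = 0.0587). Hbb, at 1248 ± 288 CPM in controls (SD, n = 3), had a log2 fold change of 0.26. Of 9 cardiac muscle genes, 0 passed with edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.486), and 0 with limma-voom. At an unadjusted p under 0.05 there was 1, Pln, with a log2 fold change of 1.05 (adjusted p = 0.0565). Pln was called higher with DESeq2 (adjusted p = 0.0108), with no filter (adjusted p = 0.0496) and with the replicate number as a block (adjusted p = 0.037). It was also called without control replicate 3 (adjusted p = 0.041) or MCT replicate 2 (adjusted p = 0.0392).

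Inflammatory mediators were higher on balance. In the chemokines and cytokines list 11 of 28 tested members rose, 2 fell and 15 did not pass, against 16 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.000189, but adjusted p = 0.438 with an estimated correlation). Cxcl9 rose 4.42-fold, and Ccl2, which draws monocytes, rose by 3.92 (log2), or 3.07 without MCT replicate 1, and was not called with limma-voom (adjusted p = 0.0662). Il33, an alarmin kept in lung epithelium and endothelium, fell 2.18-fold, and Ccl5, outside the rule, fell by 1.53 (log2). The call of Ccl5 ended without control replicate 2 or 3 or MCT replicate 1 or 3 (adjusted p = 0.0523 to 0.0727). In the complement list 11 of 20 rose, 0 fell and 9 did not pass, against 11 higher and 2 lower adjusted over the list alone (camera adjusted p = 6.95e-10, but adjusted p = 0.123 with an estimated correlation). Cfi rose 6.31-fold and C5ar1 3.01-fold, and C4a rose 3.34-fold, though reads of C4a and its copy C4b may be shared.

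In the MHC class II presentation list 4 of 13 tested members rose, 0 fell and 9 did not pass, with 5 higher adjusted over the list alone (camera adjusted p = 8.52e-05, but adjusted p = 0.132 with an estimated correlation). The protease gene Ctss and the costimulatory genes Cd80 and Cd86 rose 2.89-fold, 4.93-fold and 3.05-fold, RT1-DMb, outside the rule, rose by 0.92 (log2), and Cd74, the invariant chain, had a log2 fold change of 0.31 (adjusted p = 0.228). Of 23 interferon response genes 2 fell, 0 rose and 21 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0507). That list was called lower without control replicate 1 (adjusted p = 0.00274), control replicate 2 (adjusted p = 0.0361) or MCT replicate 2 (adjusted p = 0.000462), with no filter (adjusted p = 0.03) and with the replicate number as a block (adjusted p = 0.0407). Herc6 and Ifi44l fell by 0.85 and 1.03 (log2), calls that ended without any 1 of the controls, MCT replicate 1 or MCT replicate 3 (adjusted p = 0.0512 to 0.132). Ifi27, its most abundant member, had a log2 fold change of 0.19 (adjusted p = 0.627).

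Signalling genes linked to the disease moved in both directions. In the BMP and TGF-beta list 6 of 41 tested members rose, 4 fell and 31 did not pass, against 7 and 5 adjusted over the list alone (camera adjusted p = 0.913). The list's median was 0.0101 and its mean 0.0393, while camera's direction was down. Bmp6 fell 2.1-fold and the inhibitory Smad6 1.81-fold, and Fstl3 rose 1.83-fold. Id3, outside the rule, fell by 0.45, a call that ended without control replicate 2 or 3 or any 1 of the MCT samples (adjusted p = 0.0733 to 0.152), with no filter and on both FPKM scales (adjusted p = 0.0521 to 0.054). Of 14 tested genes of heritable pulmonary arterial hypertension 4 fell, 0 rose and 10 did not pass, also adjusted over the list alone (camera adjusted p = 0.000664, but adjusted p = 0.221 with an estimated correlation). Sox17 fell 1.98-fold and Klf2, a flow-responsive transcription factor gene, 1.95-fold. Gdf2, the gene of BMP9, had 48 counts over the controls and 0 over the MCT samples, at least 15.8-fold lower against a floor of 3 counts over the group, and the list's median was -0.403 with or without this bound. Bmpr2, outside the rule, fell by 0.67, a call that ended without control replicate 1 (adjusted p = 0.0689), control replicate 3 (adjusted p = 0.102), MCT replicate 1 (adjusted p = 0.081) or MCT replicate 3 (adjusted p = 0.0949).

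Of 39 tested vasoactive signalling genes 7 rose, 5 fell and 27 did not pass, against 9 and 7 adjusted over the list alone (camera adjusted p = 0.913). The median was 0.0451 and the mean 0.134, while camera's direction was down. Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, rose from 0.653 ± 0.255 to 17.8 ± 10.6 CPM (SD, n = 3), and the cyclooxygenase gene Ptgs1 rose 1.89-fold. The log2 fold change of Tph1 was 4.77 in the main test and 2.12 at its lowest over the alternatives. The members that fell were Calcrl 4.32-fold and, outside the rule, Pde3a by 1.42, Edn3 by 1.32, Ace by 1.11 and Slc6a4 by 0.89 (log2). The calls of Edn3, Ace and Slc6a4 ended without control replicate 2 or 3, those of Edn3 and Slc6a4 also without control replicate 1 or MCT replicate 3, and those of Edn3 and Ace without MCT replicate 1 (adjusted p = 0.0573 to 0.167). That of Edn3 ended with the stricter filter as well (adjusted p = 0.0515). Of 32 growth factor and receptor genes 2 rose, 5 fell and 25 did not pass, against 2 and 6 adjusted over the list alone (camera adjusted p = 0.331). The median was 0.00486 and the mean -0.0365, with camera's direction down. Hey1, a Notch target, fell 3.42-fold, Igf1 rose 3.49-fold and Pdgfc 2.36-fold, and Vegfa had a log2 fold change of -0.53 (adjusted p = 0.151) and was called lower without MCT replicate 2 (adjusted p = 0.0427). Outside the rule, Fgfr2 fell by 1.15, Met by 0.86, Hgf by 0.59 and Pdgfd by 0.54 (log2). Each of these 4 calls ended without control replicate 2 or 3. Those of Hgf and Pdgfd ended also without control replicate 1, those of Met, Hgf and Pdgfd without MCT replicate 1, and those of Fgfr2, Hgf and Pdgfd without MCT replicate 3 (adjusted p = 0.0518 to 0.128). On both FPKM scales Pdgfd was not called (adjusted p = 0.0517 and 0.0506).

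In the glycolysis and hypoxia response list 6 of 24 tested members rose, 1 fell and 17 did not pass, against 8 and 1 adjusted over the list alone (camera adjusted p = 0.00497, but adjusted p = 0.221 with an estimated correlation). Gapdh and Eno1, enzymes of glycolysis, rose 2.17-fold and 1.68-fold. Epas1, a hypoxia-inducible factor gene abundant in endothelium, fell from 3247 ± 284 to 1532 ± 354 CPM (SD, n = 3), a call that ended without control replicate 2 (adjusted p = 0.0531). Of 20 fatty acid oxidation genes 1 fell, 0 rose and 19 did not pass, and 0 passed adjusted over the list alone (camera adjusted p = 0.435). The gene that fell was Ppargc1a, by 1.40, a call that ended without any 1 of the controls, MCT replicate 1 or MCT replicate 3 (adjusted p = 0.0645 to 0.147). In the oxidative stress list 9 of 23 rose, 0 fell and 14 did not pass, against 11 adjusted over the list alone (camera adjusted p = 0.000392, but adjusted p = 0.123 with an estimated correlation). Hmox1, the gene of the haem-degrading enzyme haem oxygenase 1, rose 5.53-fold, and the NADPH oxidase subunit genes Cybb and Cyba rose 1.8-fold and 1.85-fold.

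Of 20 immediate early and stress genes 6 rose, 0 fell and 14 did not pass, against 7 adjusted over the list alone (camera adjusted p = 0.000561, but adjusted p = 0.334 with an estimated correlation). Cyr61 rose 2.97-fold and Junb 2.18-fold, and Jun had a log2 fold change of 0.25 (adjusted p = 0.206). Of 18 circadian clock genes 2 rose, 2 fell and 14 did not pass, against 3 and 3 adjusted over the list alone (camera adjusted p = 0.556). Bhlhe41 rose by 1.36, Nfil3, outside the rule, rose by 0.76, and Per3 fell by 0.75, and each call ended without control replicate 2 or 3 or MCT replicate 3, those of Nfil3 and Per3 also without MCT replicate 1 (adjusted p = 0.055 to 0.159), with limma-voom and on both FPKM scales (adjusted p = 0.0502 to 0.0889), and that of Nfil3 with the stricter filter (adjusted p = 0.051). The clock repressor Nr1d2 stood at 104 and 95.4 CPM in control replicates 2 and 3, but at 29.9 CPM in control replicate 1 and at 24.3, 27.6 and 24.7 CPM in the MCT samples. Its call (log2 fold change -1.58, adjusted p = 0.0328) ended without control replicate 2 (adjusted p = 0.114), control replicate 3 (adjusted p = 0.111), MCT replicate 1 (adjusted p = 0.0893), MCT replicate 2 (adjusted p = 0.053) or MCT replicate 3 (adjusted p = 0.0966), and with limma-voom and on both FPKM scales (adjusted p = 0.0759 to 0.0781). Fkbp5, a glucocorticoid-induced gene outside the rule, stood at 191 CPM in control replicate 1, at 46.4 and 19.8 CPM in the other controls and at 230, 286 and 220 CPM in the MCT samples, and was called higher without control replicate 1 (log2 fold change 2.90, adjusted p = 0.00795).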

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

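Pbk was higher and called under all 15 alternatives (log2 fold change 2.11 to 2.92, adjusted p 4.95e-21 to 0.00793), with 2.63 to 2.92 when 1 sample was left out. Leaving out 1 sample gave 481 to 1394 genes higher and 212 to 978 lower, 390 to 834 higher and 165 to 508 lower by at least 2-fold, 15 to 16 lists higher and 6 to 9 lower. Fewer samples leave fewer degrees of freedom, but leaving out MCT replicate 2 raised the counts, and the cause was not tested. That sample lay nearest the controls on the first principal component, at 24.2, against 63.6 and 39.1 for MCT replicates 1 and 3. Under an adjusted p of 0.01 there were 401 genes higher and 144 lower, 336 and 117 by at least 2-fold. On log2(FPKM + 1), a scale that shrinks changes of low genes, 425 and 193 genes passed 2-fold. The other alternatives kept these counts within 1.5 times. DESeq2 called 2743 genes, 1981 of them among the 2000. Of the 2000 calls, 64.8%, 40% and 33.9% were kept without control replicates 1 to 3, and 50.9%, 84.4% and 50.5% without MCT replicates 1 to 3. In each of the 15 alternatives with the threshold of 0.05, 0 shared calls had the opposite sign. Calls shared by fits of overlapping samples can hardly turn, so this says little on how stable they are. With an estimated correlation 4 lists stayed higher and 1 lower, and fry, which tests a list by itself, called 12 and 2. Of the genes followed under the alternatives, DESeq2 left 188 on the same side of the threshold with 10 more called and 2 fewer, and limma-voom 189 with 10 fewer. Median-of-ratios size factors left 202, library sizes only 199, no filter 198, the stricter filter 189, and the scales log2(FPKM + 1) and log2(FPKM + 0.1) 182 and 181. Leaving out control replicate 2 or 3 ended 45 calls each. Depth limits genes of few counts, such as Pbk with 30 to 50 counts in each control sample.

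The values gave no sign that the replicate numbers pair the samples. Deviations of same-numbered samples from their group means correlated at -0.0583, -0.0695 and -0.00241, and those of other pairs at -0.0755 to 0.126. Of the 3 controls, 0 correlated best with the MCT sample of its own number. With 3 samples per group this check cannot exclude pairing, such as a shared litter or day. With the number as a block there were 917 genes higher in MCT lung and 546 genes lower in MCT lung, and 15 lists were higher and 8 lower. Of the followed genes, 20 were no longer called and 3 were newly called under the block, and the interferon list was called lower. The calls that ended included Postn, Limch1, Lmo7, Rtkn2, Abca3, Bpifb1, Kit, Slc4a1, Ifi44l and Ppargc1a (adjusted p = 0.0579 to 0.0959). Outside the rule, those of Lyve1, Bmpr2, Ms4a1, Cd79b, Nfil3, Id3, Edn3 and Pdgfd ended as well (adjusted p = 0.055 to 0.0876). The block turned the sign of the Vwf log2 fold change (-0.069), Tsc22d3 (0.311), Per1 (0.231) and the vasoactive list (adjusted p = 0.954), none of which was called.

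Other reversals also concerned results that were not called, and the cause was not tested. The Vwf log2 fold change was -0.069 with limma-voom, -0.011 with library sizes only, -0.071 on log2(FPKM + 1) and -0.074 on log2(FPKM + 0.1). Tsc22d3 stood at 0.24, and Per1 at 0.256, with limma-voom, at 0.246 and 0.198 on log2(FPKM + 1), and at 0.25 and 0.227 on log2(FPKM + 0.1). Direction turned with fry for the BMP and vasoactive lists (adjusted p = 0.956 for both) and with no filter for the cardiac (0.77) and vasoactive (0.874) lists. When 1 sample was left out, log2 fold changes ran from -0.016 to 0.399 for Pdpn, -0.507 to 0.586 for Hbb, -0.097 to 0.349 for Ifi27, -0.002 to 0.427 for Cd59, -0.161 to 0.539 for Ccnb2, -0.38 to 0.18 for Vwf, -0.248 to 0.438 for Pecam1, -1.073 to 0.299 for Wt1, -0.688 to 1.01 for Tsc22d3, -0.023 to 2.429 for Zbtb16, -0.441 to 0.687 for Per1 and -0.046 to 0.925 for Cry1. Adjusted p of lists that turned ran from 0.752 to 0.912 (fibroblast), 0.057 to 0.996 (club), 0.00231 to 0.865 (ciliated), 0.134 to 0.999 (cardiac), 0.645 to 0.984 (BMP) and 0.65 to 0.956 (vasoactive).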

Other observations

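The pathway test and its repeat, both mast cell tests, the test of a common endothelial fold and the 3 tests on control replicate 1 were chosen only after the result was seen. KEGG pathways were tested among 4859 tested genes with a pathway, of which 509 were higher and 224 lower in MCT lungs. The test treats genes as independent, though genes that vary together between samples tend to be called together. Its p-values, here and in the next paragraph, therefore do not measure the spread between samples. Genes of the phagosome were higher in 42 of 145 cases, where 15.2 are expected (hypergeometric test, Benjamini-Hochberg adjusted p = 5.93e-08 over 211 pathways), and 9 were lower, where 6.68 are expected. Genes of the lysosome were higher in 35 of 117, where 12.3 are expected (adjusted p = 3.79e-07). The pathways described here are not all that passed this test. Others among higher genes included complement and coagulation cascades (adjusted p = 2.37e-06) and cell cycle (adjusted p = 0.00022). The p53 signalling pathway (adjusted p = 0.000896) and cytokine-cytokine receptor interaction (adjusted p = 0.00172) passed too, and Hippo signalling passed among lower genes. Lysosomal genes that rose included the cathepsin gene Ctsz 2.43-fold, the legumain gene Lgmn 2.15-fold and Psap, whose product yields the saposins, from 983 ± 147 to 1919 ± 16.4 CPM (SD, n = 3). These 3 genes are outside the rule and were chosen after their values were seen. The renin-angiotensin pathway had 9 higher genes of 20 (adjusted p = 0.00248) and 3 lower, among the higher the mast cell genes Cma1, Cpa3, Mcpt8 and Mcpt8l2, with Prcp, a peptidase outside the rule, at 1.72-fold.

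Among lower genes, Rap1 signalling held 23 of 179, where 8.25 are expected (adjusted p = 0.000718), while 18 others were higher, where 18.8 are expected. The pathway of stem cell pluripotency signalling held 17 lower loci of 108, where 4.98 are expected (adjusted p = 0.000718), with 4 higher. Some of these loci are copies, such as Fzd8 and a locus with identical counts, and with 1 locus per symbol the pathway held 15 of 106 (adjusted p = 0.00585). Neuroactive ligand-receptor interaction held 16 lower of 119 (adjusted p = 0.00662) and also 16 higher, where 12.5 are expected. Chosen after their values were seen and outside the rule, Rap1gap fell 2.84-fold, the ephrin gene Efna1 1.83-fold (both in Rap1 signalling), the cytokine receptor gene Lifr 4.39-fold and the Wnt receptor gene Fzd4 2.45-fold (both in stem cell signalling), and the leptin receptor gene Lepr 3.93-fold (among neuroactive receptors). Natural killer cell cytotoxicity held 13 lower of 104, where 4.79 are expected (adjusted p = 0.037), and 14 higher, where 10.9 are expected (adjusted p = 0.844). The lower genes were in part RT1 class I genes, whose reads can be shared between copies. With 1 locus per symbol the 7 results for phagosome, lysosome, renin-angiotensin, Rap1, stem cell, neuroactive and natural killer cell pathways stayed past the threshold (adjusted p = 2.58e-07 to 0.0448). That repeat merges only loci with the same symbol or identical counts. Copies with other symbols, such as Mcpt8 and Mcpt8l2 or the RT1 genes, were still counted apart.

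Mast cell transcripts rose in lungs where 8 of 24 T and NK cell genes fell. Reads shared between protease copies would leave other members near 0, but the 7 members outside the chymase and tryptase families had a median log2 fold change of 2.03, with 5 called higher. Lymphoid tissue in the MCT pieces would bring T and NK cell transcripts, and that list's median was -0.731. A fall of these transcripts in the lung itself could mask such an addition, so the median does not exclude it. More mast cells in MCT lungs is a hypothesis that these tests leave open, beside more transcript per cell, which was not tested. Kit and Gata2, also made by other lung cells, were lower, calls that ended when single samples were left out (Kit without control replicate 2 or 3 or MCT replicate 2 or 3, Gata2 without control replicate 2 or MCT replicate 1 or 3, adjusted p = 0.0639 to 0.113).

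Log2 fold changes of the endothelium list ran from -2.38 to 0.32, with 7 of 19 tested members lower and 12 not past the threshold. A lower share of endothelial cells as the whole cause would give about 1 common fold only if no other lung cells made these transcripts, which was not tested. Cochran's Q was 10.4 times its degrees of freedom (187 on 18), so the 19 members did not share 1 fold. This Q measures the spread already seen and treats the members as independent, though their estimated correlation was 0.549. It therefore does not decide on a lower share. Gene length does not account for the spread, since the SD after taking out the trend on length was 0.958 of that before. A lower share of endothelial cells, a change of transcript levels within them, or of the balance of their subtypes, may contribute. Bulk tissue leaves each of these open.

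Control replicate 1 stood apart from the other controls in clock and glucocorticoid-induced genes, and lay nearer to the MCT samples in several. On the second principal component, with 14.5% of the variance, it lay at 29.1, close to MCT replicate 2 at 30.6. Control replicates 2 and 3 lay at -18.9 and -19, and MCT replicates 1 and 3 at -21.1 and -0.672. The cause of this axis, which crosses the groups, was not tested. Were control replicate 1 from an MCT lung, its mitosis genes should be raised, but their median against the other controls was 0.139, against 1.96 for the MCT samples. A glucocorticoid response at handling stays open: Fkbp5, Tsc22d3, Sgk1, Zbtb16 and Per1 had a median log2 difference of 2.47 from the other controls, but these genes were chosen after their values were seen, Sgk1 had 0.07 and the other controls differed from each other by 1.23 in Fkbp5 and 2.1 in Zbtb16. Another time of day cannot be told apart from it, since 4 of 5 clock genes, chosen in the same way, moved as it predicts by more than the other controls differed, Dbp did not, and the labels used here give no collection times. Without this sample Fkbp5, Zbtb16, Per2, Cry1 and Nr1d1 became called (adjusted p = 0.00795, 0.0383, 0.0252, 0.0441 and 0.007). Nr1d1 was also called with DESeq2, library sizes only, no filter and the block (adjusted p = 0.0191 to 0.0487). Against control replicates 2 and 3, the MCT samples had log2 differences of -3.4 in Nr1d1, -1.97 in Nr1d2, -0.59 in Dbp, 1.66 in Per2 and 0.9 in Cry1. In Fkbp5, Zbtb16, Sgk1, Tsc22d3 and Per1 the differences were 3.01, 2.7, 1.27, 1.08 and 0.81. Sgk1 was called higher with all samples (log2 fold change 1.25, adjusted p = 0.00433). Whether hour or handling also differed between the groups was not tested, so part of the MCT contrast may reflect either.

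The 6 samples allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2000 genes and 1 was the highest of the others, and 1039 genes by at least 2-fold against 1. In lists it called 22, and the others called 6 to 22 with the preset correlation. Thus 2 of the 10 splits, the real one included, reached 22. The other splits mix the groups unevenly, so they are not free of the group difference. Still, camera called lists where 0 or 1 genes passed, so its adjusted p-values with the preset correlation do not by themselves mark a group difference.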
